A study of Lytechinus variegatus with 7 samples.

How the data were processed

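The values are counts of unique molecular identifiers (UMIs) for each gene model and cell barcode, which the authors made with 10x Cell Ranger from 3' v3.1 single-cell libraries of methanol-fixed cells. The submitters' notes name Cell Ranger 3.1.0 and Seurat 4.0, while per the file headers the deposited matrices come from Cell Ranger 6.1.2, and which version made these counts is not settled here. The genome build and annotation are not given in the sources used here, so no positions are given. Of 27658 gene models 22489 carry a name, of which 12707 are distinct, so several models share a name and are counted as separate models. A reference table of gene names could not be linked to these gene models and was not used. The lowest number of genes in a cell lies above 200, so the 200-gene minimum removed 0 cells, and all 19205 deposited barcodes entered the tests.

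Counts were summed over the cells of each library. The slope in labelled hours was tested with edgeR 4.0.16 (quasi-likelihood F test, TMM, R 4.3.3) for gene models with at least 10 summed counts in at least 3 libraries, which left 5 residual degrees of freedom. Cells with at least 1 alx1 UMI and cells with none were summed separately in each library with at least 10 of each, and compared by the same test with the library as a block, alx1 itself left out. Standard errors (SE) are the size of the slope or log2 fold divided by the square root of its F statistic, not spreads over library values. The Benjamini-Hochberg threshold was 0.05 throughout. The other tools were DESeq2 1.42.0 and limma 3.58.1 (voom, camera with a preset correlation of 0.01 and with an estimated one, and fry). The test in time was also tested on simulated data: with a slope of 0.1, 0.2 or 0.4 log2 per hour added it found 6.06, 50.0 and 100% of such genes, with 6.42% false calls. All simulated genes had the same dispersion and straight slopes, so these rates may not hold for the real genes. For cells with alx1 a log2 fold of 1, 2 or 3 was found in 43.9, 90.9 and 100%, with 3.75% false calls. Odds ratios were tested on simulated data too, and true log2 values of 0, 2 and 4 came back as 0.04, 1.98 and 3.87.

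The 20 lists cover skeletogenic regulators, biomineralization, early micromere, pigment cell, blastocoelar, non-skeletogenic mesoderm, muscle and coelomic, germline, endoderm, veg1 and Wnt, oral ectoderm, aboral ectoderm, apical and neural, ciliary band, Vegf, Fgf and Nodal signals, Notch, hatching blastula, cell cycle, stress and ribosomal protein genes. Names were matched before any value was read, and 299 of 335 list genes were found. Some genes sit in more than 1 list, so the lists are not independent. The lists, the tests, the cell class markers and most alternatives were chosen before the data were examined.

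Named genes follow a rule fixed then. For time they are the 10 steepest rising and 10 steepest falling named models past the threshold with a mean of at least 20 CPM. For cells with alx1 they are the 15 highest and 8 lowest that changed the same way in every library used, with at least 10 CPM in the higher class.

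Shares of cells were also computed after thinning each cell to 1000 UMIs, which leaves out 38, 6, 168, 23, 21, 315 and 79 cells of the 7 libraries. Odds ratios are Mantel-Haenszel values over 10 strata of the UMI count, for libraries with at least 5 cells of each gene, and were tested by an exact two-sided sign-flip permutation. The pair alx1 with sm50 had only 2 such libraries and was not tested. Clusters are Leiden clusters at resolution 1 (scanpy 1.11.5, igraph 0.11.9) on 2000 variable genes, 30 components and 15 neighbours without integration. A cluster was named when at least 3 fixed markers of a class, and more than of any other class, were at least 2-fold higher in it, at 20 CPM or more. No other class could have more markers among the cluster's 10 leading genes. A cluster without a leading marker of its class also stayed unnamed if its cells held under 0.333 of the median UMI count of their libraries. A cluster holding over 50% of a library was left unnamed, a rule set after the data were seen, which applied to 1 cluster with 79.1% of the cells at 6 hpf.

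Doublets were kept. Scrublet (through scanpy) marked 17, 8, 3, 12, 13, 0 and 0 cells from 6 to 18 hpf, which leaves few or no marks at 10, 16 and 18 hpf, where its performance was not tested, and removing its marks is given as an alternative. Removing the top scores at a fixed rate of 0.8% per 1000 cells was added after the data were seen. Other choices made after the data were seen are the fits without the libraries labelled 8 and 10 hpf, with their times exchanged, with 14, 16 and 18 hpf alone and without the deepest barcode at 18 hpf, the profile of cells with at least 2 alx1 UMIs, and the test of how the alx1 difference changes with age. Calculations used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.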

Results

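Messenger RNA was profiled in single cells of embryos of the sea urchin Lytechinus variegatus whose micromeres had been removed by surgery. Micromeres are the vegetal cells that normally found the larval skeleton, and the series asks how other cells are reprogrammed when this lineage is missing. The 7 libraries form 7 groups of 1, labelled 6, 8, 10, 12, 14, 16 and 18 hours post fertilization (hpf), and no unoperated embryos were analysed here. In that order they held 387, 103, 4239, 1237, 1930, 7704 and 3605 cells, and 6627148, 652661, 10758202, 5501169, 9505633, 23160718 and 12174119 UMIs. The median cell held 15987, 5500, 2224, 3986, 4216, 2609 and 2813 UMIs. Without replicates no pair of ages was tested against each other. The tests are slopes over the libraries, and comparisons between cells of the same library with libraries as replicates. Intervals are 95% (Poisson for levels, Clopper-Pearson for shares of cells), and intervals and floors cover counting error only.

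The first comparison asked which genes change with labelled age. Among the named genes that rose was GataC (gene model LVA_32108.t1), a GATA factor of the blastocoelar lineage, by 0.76 ± 0.11 log2 per hour (SE, n = 7 libraries; edgeR adjusted p = 0.009996), from 0.754 CPM (counts scaled to the library total) at 6 hpf to 133 at 18 hpf. Scl, a bHLH factor of blood and mesoderm, rose by 0.75 ± 0.12 per hour (edgeR adjusted p = 0.0123), from 3.17 to 274 CPM. P16, a membrane protein of skeletogenic cells, rose by 0.74 ± 0.15 (edgeR adjusted p = 0.0218), and Ars, arylsulfatase of the aboral ectoderm, rose by 0.66 ± 0.16 (edgeR adjusted p = 0.0321), from 1.96 to 917 CPM. He1, named as a hatching enzyme, fell by 1.00 ± 0.18 per hour (edgeR adjusted p = 0.0152), from 2086 to 1.07 CPM, and the early histone EhH1_29 fell by 0.88 ± 0.11 (edgeR adjusted p = 0.00870), from 2774 to 2.71 CPM.

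By the fixed rule the other named rising genes were Fabp2L2 (0.92 ± 0.10 log2 per hour, 0.604 to 132 CPM), Cuzd1L_1 (0.69 ± 0.06), Lct_3 (0.64 ± 0.07) and Gat_2 (0.62 ± 0.07), each with an edgeR adjusted p of 0.00814, Dr_1 (0.59 ± 0.08, adjusted p = 0.00948) and Glyt_3 (0.57 ± 0.13, adjusted p = 0.0292, 28.4 to 3447 CPM). The other named falling genes were both models of the astacin-family protease An (-0.98 ± 0.17 and -0.96 ± 0.22, edgeR adjusted p = 0.0141 and 0.0295), Ddc_1 (-0.90 ± 0.20, 0.0264), both models of the histone EhH3_57 (-0.79 and -0.75, 0.00837 and 0.00814), the histone ClvhH1 (-0.78 ± 0.09, 0.00814), Mmp1/3L1 (-0.74 ± 0.18, 0.0325) and Rxfp2L_4 (-0.73 ± 0.15, 0.0206). Of these 20 gene models 9 passed with any 1 library left out: Fabp2L2, GataC, Cuzd1L_1, Lct_3, Gat_2, Dr_1, EhH1_29 and both EhH3_57. Calls ended with the highest adjusted p at 0.0600 for Scl (6 or 16 hpf left out), 0.0832 for P16 (6, 16 or 18), 0.0918 for Ars (6, 8, 10, 14 or 16), 0.113 for Glyt_3 (6, 14, 16 or 18), 0.0889 for He1 (6 or 16), and 0.0805 (6 or 16) and 0.113 (6, 14, 16 or 18) for the An models. They ended likewise at 0.107 for Ddc_1 (6, 14, 16 or 18 hpf left out), 0.0624 for ClvhH1 (6), 0.119 for Mmp1/3L1 (6, 14, 16 or 18) and 0.0916 for Rxfp2L_4 (6, 16 or 18).

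Of 18039 gene models tested, 1012 rose and 1001 fell, and 5474 had an unadjusted p under 0.05. The counts rested on single libraries: 330 rose and 101 fell without 6 hpf, 1323 and 1662 without 8 hpf, 438 and 252 without 14 hpf, 65 and 12 without 16 hpf, and 202 and 129 without 18 hpf.

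Among 20 lists of genes fixed beforehand, 5 moved up and 1 down relative to other genes (camera with a preset correlation), and none of the 6 with an estimated one. Members named within lists were chosen after their values were seen. Of 24 endoderm genes 6 rose, 18 did not pass, and 6 rose adjusted over the list alone (adjusted p = 2.77e-05; adjusted p = 0.251 with an estimated correlation). They were Endo16, a secreted gut protein (0.51 ± 0.10, from 63.1 to 2368 CPM), both Lox models (0.62 and 0.51), Unc4.1_1 (0.46), the hindgut regulator Cdx (0.30) and Gsn (0.20). Of 24 regulators of non-skeletogenic mesoderm 4 rose, both GataC models, Scl and FoxL1 (0.55), 20 did not pass, and 6 rose adjusted over the list alone (adjusted p = 0.00362; adjusted p = 0.251 with an estimated correlation). Of 16 blastocoelar genes the GataC models and Scl rose, 13 did not pass, and 6 rose adjusted over the list alone (adjusted p = 0.0171; adjusted p = 0.251 with an estimated correlation). Without the 8 hpf library the blastocoelar list had an adjusted p of 0.0648. Of 11 muscle and coelomic genes FoxL1 alone rose, over all genes and adjusted over the list alone, and 10 did not pass (adjusted p = 0.0172; adjusted p = 0.366 with an estimated correlation). That list's call ended without 8 hpf (0.0648), 10 hpf (0.0522), 14 hpf (0.0668), 16 hpf (0.109) or 18 hpf (0.377).

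Ribosomal protein genes were the broadest group. Of 81 models 59 rose, 22 did not pass, and 76 rose adjusted over the list alone, Rps16 by 0.45 and Rpl26 by 0.32 log2 per hour (adjusted p = 1.24e-47; adjusted p = 0.251 with an estimated correlation). They held 0.256, 1.48, 0.437, 1.503, 2.99, 4.19 and 5.44% of all UMIs from 6 to 18 hpf. The list of hatching blastula genes moved down: the cyclin B models Cycb_1 (-0.25 and -0.24) and Cycb3 (-0.15) fell, 3 of its 6 members did not pass, and 5 fell adjusted over the list alone (adjusted p = 0.00125; adjusted p = 0.251 with an estimated correlation). These are cell cycle genes, and the hatching enzyme He1 was not matched to the list.

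The skeletogenic lists did not pass as lists with age. Of 26 biomineralization genes Sm29, a spicule matrix protein (0.47 ± 0.06, edgeR adjusted p = 0.00837), and P16 rose, the bicarbonate transporter Slc4a10 fell (-0.13), 23 did not pass, and 2 rose and 1 fell adjusted over the list alone (adjusted p = 0.0828). That list passed without the 8 hpf library (0.000663) or without the 14 hpf library (0.0131). Of 18 skeletogenic regulators Alx1 rose (0.42 ± 0.10, edgeR adjusted p = 0.0293), both Smad1/5/8_1 models fell, 15 did not pass, and 4 rose and 3 fell adjusted over the list alone (adjusted p = 0.707). Of 10 early micromere genes the Notch ligand Delta (0.28 ± 0.04) and Tcf (0.24) rose and 8 did not pass, with 2 up and 1 down adjusted over the list alone (adjusted p = 0.713); its median slope was slightly negative while the test pointed up.

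The remaining lists did not pass either. Of 32 cell cycle genes 4 rose, among them Pcna (0.17) and Mcm5 (0.18), 7 fell, among them CycA (-0.31) and Cdc20, and 5 and 12 did adjusted over the list alone (adjusted p = 0.124). Of 15 ciliary band genes Btub3 rose (0.31) and 5 fell, among them tektins and SoxB2, with 1 and 6 adjusted over the list alone (adjusted p = 0.128). In the aboral ectoderm list (14 genes, adjusted p = 0.265, 0.0478 without 18 hpf) Ars rose. In the pigment cell list (22 genes, adjusted p = 0.265) Mitf rose (0.22), and in the Notch list (10 genes, adjusted p = 0.538) Delta rose; adjusted over the list alone each of these 3 lists had 1 rising gene. In the veg1 and Wnt list (16 genes, adjusted p = 0.265, 0.0144 without 6 hpf) Wnt3 rose (0.21) and Wnt16 fell (-0.22), also adjusted over the list alone. In the oral ectoderm list (12 genes, adjusted p = 0.707, 0.0292 without 6 hpf) Univin fell (-0.25), and in the apical and neural list (17 genes, adjusted p = 0.776) SoxB2 fell (-0.18), each also adjusted over the list alone. The test pointed down for both of these lists, while the oral median and the apical mean were positive. Bmp5-8 fell (-0.20) in the list of Vegf, Fgf and Nodal signals (17 genes, adjusted p = 0.726) but not adjusted over the list alone. In the stress list (17 genes, adjusted p = 0.707) GadD45 and Hsp901 rose and Egr and Fos fell, with 2 and 3 adjusted over the list alone. No germline gene of 11 passed in edgeR, over all genes or adjusted over the list alone (1 had an unadjusted p under 0.05; list adjusted p = 0.798), and the test pointed up with a median slightly below 0.

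Expression did not advance in the order of the labels: the library labelled 8 hpf was further along than the one labelled 10 hpf. Endo16 stood at 208 CPM at 8 hpf and 22.7 at 10 hpf, and FoxA, a forkhead factor of the endoderm, at 875 and 319. He1 stood at 7.66 CPM at 8 hpf and 216 at 10 hpf. Without both libraries 1001 genes rose and 1498 fell. Among the 1560 of these with a mean of at least 20 CPM over the 7 libraries, 82.1% were further along at 8 hpf (84.3% of 547 rising and 80.8% of 1013 falling genes; genes are not independent replicates). In the median cell, these rising genes held 8.62, 38.4, 18.6, 49.8, 61.0, 72.7 and 76.7% of the UMIs of rising and falling genes from 6 to 18 hpf.

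**Figure D1:**
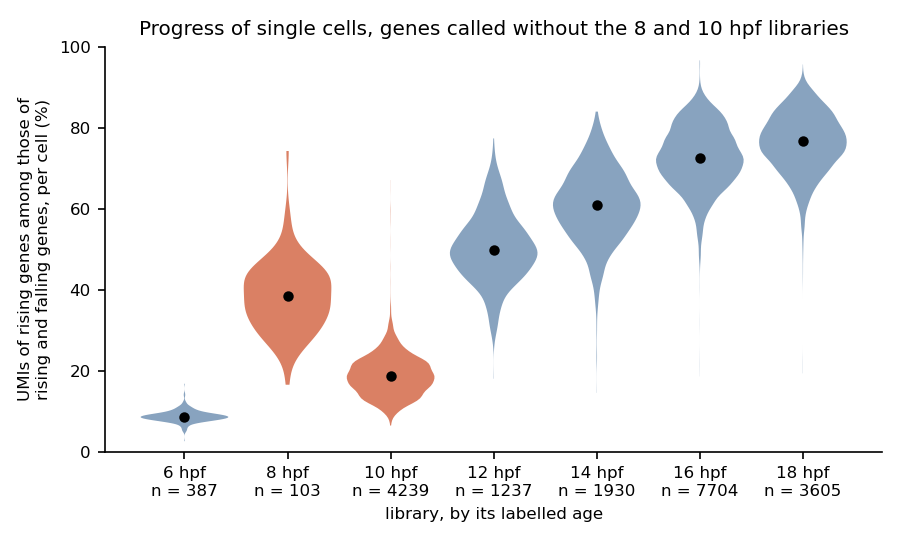
Percent of UMIs from rising genes among those from rising and falling genes in each cell, by library; genes were called without the 8 and 10 hpf libraries (orange), violins show cells and points medians. The median was 38.4% at 8 hpf and 18.6% at 10 hpf.

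The next comparison asked when regulators and products of the skeletogenic lineage appear after removal of the micromeres. Micromere descendants left after the operation were not excluded as a source of the values at 10 hpf. Alx1, a homeodomain factor required for skeletogenic fate, stood at 8.75 CPM (6.65–11.3) at 6 hpf, 76.6 (56.9–101) at 8 hpf, 19.4 (16.9–22.2) at 10 hpf, 58.4 (52.1–65.1) at 12 hpf, 311 (300–322) at 14 hpf, 407 (399–415) at 16 hpf and 235.5 (227–244.3) at 18 hpf. All 50 of its UMIs at 8 hpf were in 1 cell. Alx1 was seen in 26, 1, 74, 18, 115, 685 and 245 cells, or 6.72, 0.971, 1.75, 1.46, 5.96, 8.89 and 6.80%. After thinning every cell to 1000 UMIs the shares were 1.72, 1.03, 1.06, 1.07, 3.77, 6.05 and 3.80%. In aboral ectoderm-like cells, which should lack it, the shares were 0, 1.45, 2.49 and 1.45% at 12, 14, 16 and 18 hpf (median 3679, 3905, 2266.5 and 2453 UMIs). This class joins unlike clusters. At 12 and 14 hpf it was mostly a cluster of 818 cells named from dlx, irxa and smad6. At 16 and 18 hpf it was mostly clusters that carried tbx2/3, hox7 and msx. As a background it is therefore not the same kind of cell at all ages.

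Products of skeletogenic cells stood low at 12 and 14 hpf, when Alx1 was already present. The gene msp130, a surface glycoprotein of skeletogenic cells, stood at 2.26 CPM at 6 hpf, 152 at 8 hpf, 14.97 at 10 hpf, 0.545 at 12 hpf, 15.3 at 14 hpf, 164 at 16 hpf and 167 at 18 hpf, and p19 at 0.151, 257, 11.99, 0.727, 15.3, 336 and 665 CPM in the 7 libraries. At 8 hpf nearly all of these UMIs lay in the 1 cell with alx1, which held msp130 at 6978 CPM and p19 at 12212 CPM, against 4.70 and 0 CPM in the other 102 cells. At 18 hpf 1 barcode with 257816 UMIs held 24.99% of the msp130 UMIs, 24.8% of those of p19 and 19.01% of those of Alx1, and without it these stood at 128, 511 and 194.9 CPM. The spicule matrix gene sm50 had 0, 1, 0, 0, 0, 7 and 13 UMIs in the 7 libraries. The blastocoelar gene gatac stood at 0.754, 0, 2.51, 24.5, 104, 174 and 135 CPM over its models. At 8 hpf it had a UMI in 0 of 103 cells, which by the floor of 3 counts allows a share of cells with a UMI of up to 2.91% (3.52% by Clopper-Pearson) and sets no limit on cells expressing it. The pigment cell regulator gcm was highest at 6 hpf (39.5 CPM, 17.6% of cells) and stood at 12.9, 17.2 and 14.1 CPM at 14, 16 and 18 hpf, and its target pks1, a pigment synthase, had 10, 1, 38, 5, 13, 206 and 57 UMIs.

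**Figure D2:**
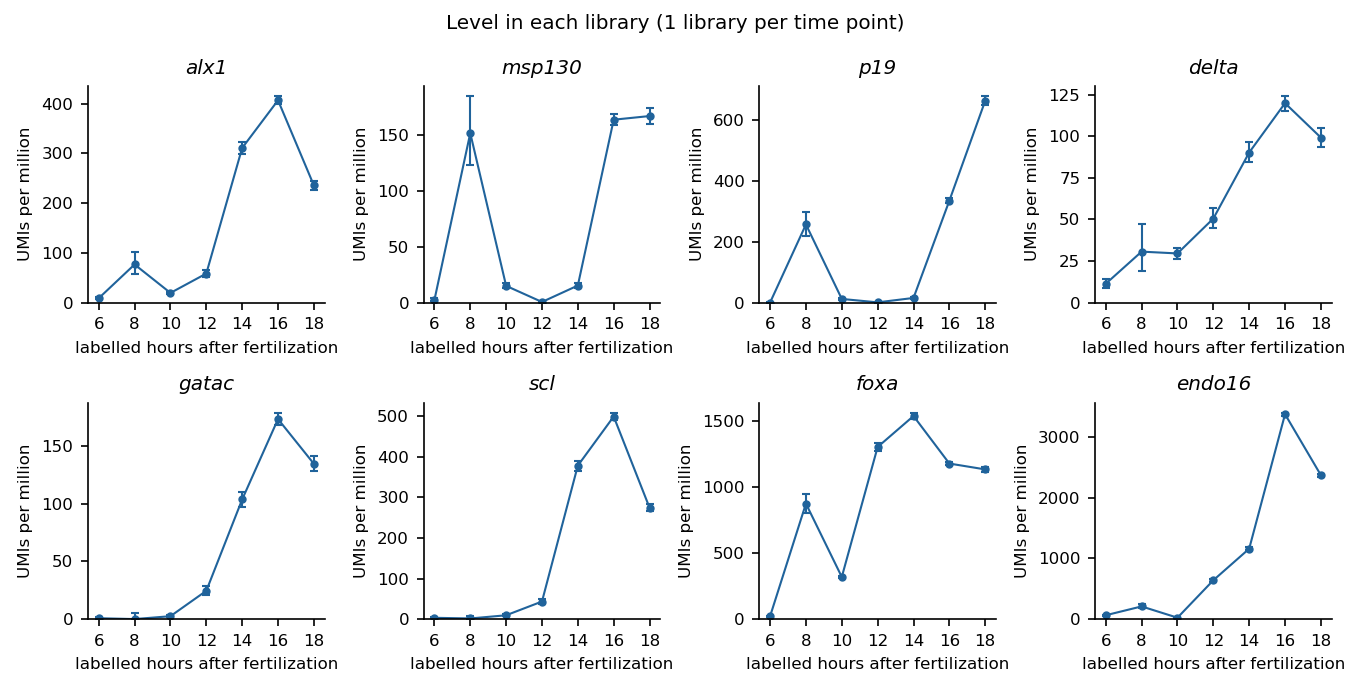
Counts scaled to the library total (CPM) against labelled hours after fertilization for 8 genes, 1 point per library, bars 95% Poisson intervals. Alx1 peaks at 16 hpf (407), and msp130 reaches 167 at 18 hpf.

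Across the 7 libraries, shares of cells thinned to 1000 UMIs were correlated with labelled age for 23 marker genes (exact permutation, two-sided). For gatac rho was 0.955 and r 0.911 (both exact p = 0.00397, adjusted p = 0.0456), and r was 0.940 without the 2 farthest samples. For scl rho was 0.955 (exact p = 0.00397, adjusted p = 0.0456) and r 0.880 (exact p = 0.0103, adjusted p = 0.0593), or 0.926 without the 2 farthest samples. For foxa r was 0.933 (exact p = 0.00317, adjusted p = 0.0456) and rho 0.929 (exact p = 0.00675, adjusted p = 0.0517), or 0.944 without the 2 farthest samples. Alx1 did not pass (rho 0.75, exact p = 0.0663, adjusted p = 0.152; r 0.754, exact p = 0.0528, adjusted p = 0.0941), and its r was 0.892 without the 2 farthest samples. With any 1 library left out no marker passed by rho (exact permutation); the adjusted p over 6 libraries has fewer orders to draw on.

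The main cellular comparison asked what cells with Alx1 express. Cells with at least 1 alx1 UMI were set against the other cells of their library in 6 libraries, the one labelled 8 hpf having a single such cell. Skeletogenic products and mesodermal regulators were both higher in the sums over these cells, which do not show that the same cells hold both. Msp130_1 was higher by 6.82 ± 0.86 log2 (SE, n = 6 libraries; edgeR adjusted p = 0.00968; mean 547 CPM with and 4.19 without). GataC was higher by 4.30 ± 0.36 (edgeR adjusted p = 0.000165; 483 and 26.1 CPM), and Erg, an ETS factor of mesoderm, by 4.05 ± 0.74 (edgeR adjusted p = 0.0311; 1926 and 96.4 CPM). The receptor Vegfr10, through which skeletogenic cells sense the ectoderm, was higher by 3.69 ± 0.60 (edgeR adjusted p = 0.0202), while the ligand Vegf3 was lower by 1.501 ± 0.33 (edgeR adjusted p = 0.0286). The Nodal antagonist Lefty was lower by 1.74 ± 0.20 (edgeR adjusted p = 1.16e-05).

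The fixed rule admits only genes that went the same way in all 6 libraries, but in single libraries the direction can rest on very few UMIs. In the 18 cells with alx1 at 12 hpf Msp130_1, Rabrp3, GrprL, B4galt6_8 and Fam20c each stood at 9.65 CPM. Univin, Galnac4s-6stL_4, Hmx and Hbn stood at 0 CPM there. At 6 hpf Vegfr10 stood at 7.88 CPM with alx1 and 7.68 without, and Fam20c at 4.73 and 4.00. Higher genes further included Rabrp3 (5.11 ± 0.45, edgeR adjusted p = 1.04e-07), Sm29 (4.41 ± 0.74, 0.0227), GrprL (4.00 ± 0.54, 0.00893), the T-box factor Tbr (3.81 ± 0.80, 0.0482), B4galt6_8 (3.71 ± 0.66, 0.0246), the secreted kinase Fam20c (3.66 ± 0.70, 0.0328), Aji (3.64 ± 0.32, 0.000135), Gulo_1 (3.34 ± 0.67, 0.0414), Ggdef (3.30 ± 0.49, 0.00250), Ets1/2 (2.99 ± 0.59, 0.0378) and Delta (2.99 ± 0.53, 0.0265). Lower genes further included Galnac4s-6stL_4 (-2.04 ± 0.32, edgeR adjusted p = 0.000286), Hmx (-1.82 ± 0.39, 0.0311), the TGF-beta ligand Univin (-1.79 ± 0.32, 0.000893), Samd8L (-1.64 ± 0.21, 2.03e-05), the dynein light chain Dynlc1-1 (-1.63 ± 0.29, 0.000768) and the homeodomain factor Hbn (-1.51 ± 0.28, 0.00139). Of the 23, 10 passed with any 1 library left out: Rabrp3 (4 of 4 such fits), GataC, Aji, Ggdef, Galnac4s-6stL_4, Univin, Lefty, Samd8L, Dynlc1-1 and Hbn. Calls ended without 16 hpf for Msp130_1 (adjusted p = 0.0581), Sm29 (0.131), GrprL (0.0701), Vegfr10 (0.0948), Fam20c (0.172), Gulo_1 (0.150), Ets1/2 (0.156) and Delta (0.0857), and without 18 hpf for Erg (0.126), Tbr (0.179), B4galt6_8 (0.121) and Hmx (0.141). The call of Vegf3 ended without 6 hpf (0.0662). Further libraries ended calls at lower adjusted p: 18 hpf for Msp130_1, 14 and 18 for Sm29, 14 for GrprL and B4galt6_8, 10, 12, 14 and 16 for Erg and Tbr, 10, 12, 14 and 18 for Vegfr10, Fam20c, Gulo_1 and Ets1/2, 6, 14 and 18 for Delta, and 10, 14 and 16 for Hmx.

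**Figure D3:**
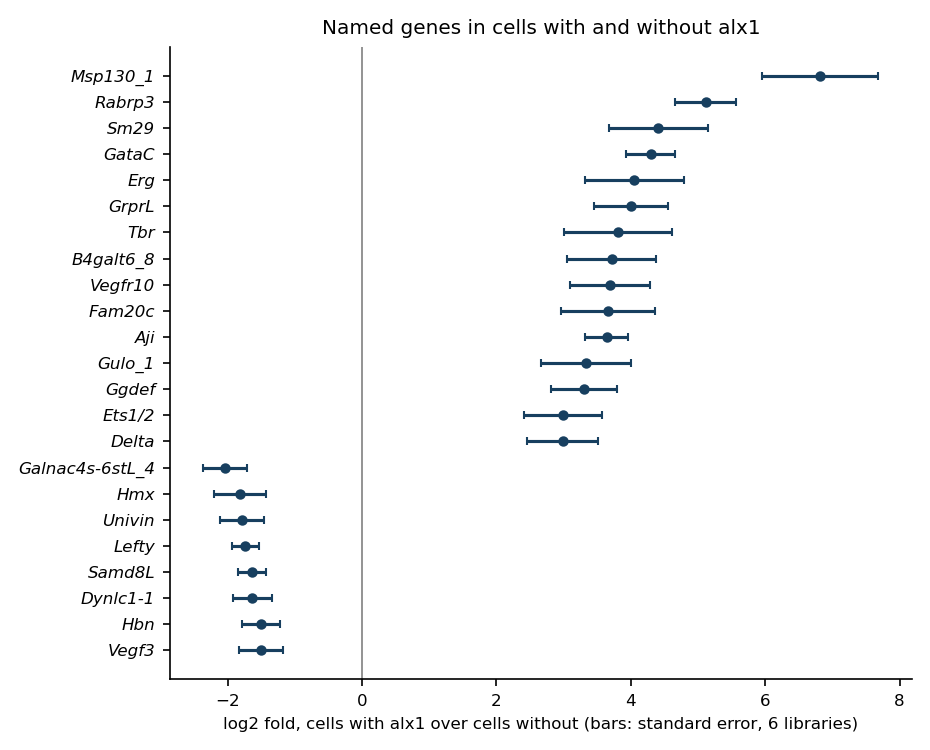
Log2 fold between cells with and without alx1 for the 23 genes named by the fixed rule, bars standard errors derived from the F statistic of the fit to 6 libraries. Msp130_1 lies farthest up at 6.82 and Galnac4s-6stL_4 farthest down at -2.04.

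Of 17882 gene models tested, 570 were higher and 1089 lower in cells with alx1, and 3776 had an unadjusted p under 0.05; DESeq2 called 632 and 783. Counts without 6 hpf were 935 and 1666, without 16 hpf 246 and 634, and without 18 hpf 282 and 599; without the replicate block for library they were 90 and 3.

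Of the fixed lists 5 were higher and 5 lower in cells with alx1, none of the 10 with an estimated correlation. Of 28 biomineralization genes 12 were higher, 2 lower and 14 did not pass, and 19 were higher and 2 lower adjusted over the list alone (adjusted p = 5.41e-11; adjusted p = 0.196 with an estimated correlation). P19 (6.86 ± 0.75), the polyketide synthase Pks2 (6.64 ± 0.29), Msp130r2 (6.33), Sm32 (5.76) and P16 (5.01) were among the higher, and the lower ones were both KirrelL models (-1.17 and -1.43), named for a protein of skeletogenic cell fusion. Of 17 skeletogenic regulators 8 were higher, among them FoxB (2.88), Snail (2.67), Tel (1.62) and FoxN2/3 (1.03), FoxJ1 was lower (-0.88), 8 did not pass, and 12 were higher and 1 lower adjusted over the list alone (adjusted p = 1.71e-10; adjusted p = 0.152 with an estimated correlation). Of 24 regulators of non-skeletogenic mesoderm 8 were higher, among them Scl (4.93 ± 0.83, edgeR adjusted p = 0.0248), both GataC models, FoxC (2.41) and FoxY (1.97), Pax2 was lower (-1.06), 15 did not pass, and 10 were higher and 1 lower adjusted over the list alone (adjusted p = 1.56e-07; adjusted p = 0.0752 with an estimated correlation). Of 16 blastocoelar genes 4 were higher, 12 did not pass, and 5 were higher adjusted over the list alone (adjusted p = 0.000219; adjusted p = 0.196 with an estimated correlation). The ribosomal list was called higher by camera (adjusted p = 0.00842; adjusted p = 0.662 with an estimated correlation), yet edgeR called no member of 81 over all genes or adjusted over the list alone (3 had an unadjusted p under 0.05), the median was 0.06, and the call ended without 16 hpf (0.170) and with cells thinned (0.187).

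Ectodermal lists were lower. Of 12 oral ectoderm genes 11 were lower, among them Chordin (-1.42), Nodal (-1.14) and Lim1 (-1.12), and 12 were lower adjusted over the list alone (adjusted p = 6.30e-15; adjusted p = 0.0752 with an estimated correlation). Of 15 ciliary band genes 11 were lower, among them both Onecut models (-1.35 and -1.43), 1 Btub3 model was higher (1.00), and 1 was higher and 13 lower adjusted over the list alone (adjusted p = 1.76e-10; adjusted p = 0.152 with an estimated correlation). Of 14 aboral ectoderm genes 9 were lower, among them Ars (-1.61), Tbx2/3 (-1.39 and -1.01) and IrxA (-1.12), 5 did not pass, and 10 were lower adjusted over the list alone (adjusted p = 4.41e-08; adjusted p = 0.152 with an estimated correlation). Of 17 apical and neural genes 8 were lower, among them FoxQ2_1 (-0.90), SoxC was higher (1.16), and 2 were higher and 10 lower adjusted over the list alone (adjusted p = 0.00168; adjusted p = 0.213 with an estimated correlation; 0.116 with cells thinned). Of 17 Vegf, Fgf and Nodal signalling genes 6 were lower, among them the ligands Vegf3, Tgfb (-1.43) and Bmp5-8 (-0.73), the receptor Vegfr10 was higher, and 1 was higher and 7 lower adjusted over the list alone (adjusted p = 0.00207; adjusted p = 0.152 with an estimated correlation).

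Endoderm genes went both ways in cells with alx1. Of 24, 5 were higher, Endo16 (1.10 ± 0.21), FoxA (0.79 ± 0.15), Blimp1 (0.57) and both Gatae models, and 5 were lower, Unc4.1_1 (-1.26), Eve (-0.93), Bra (-0.83), Gsn and Hnf1_1, with 6 and 5 adjusted over the list alone (adjusted p = 0.131, but 0.0156 without 16 hpf and 0.0491 without 18 hpf). In the pigment cell list (22 genes, adjusted p = 0.0853) 3 were higher and 2 lower, among the latter Pks1 (-1.58), with 5 and 2 adjusted over the list alone and a median of -0.01 against a test pointing up. Muscle and coelomic genes (11, adjusted p = 0.0853) had FoxC and FoxY higher, and 2 higher and 1 lower adjusted over the list alone. In the veg1 and Wnt list (16 genes, adjusted p = 0.0853, 0.000832 without 10 hpf) Nk1 (-1.37) and Eve were lower, and in the hatching blastula list (6 genes, adjusted p = 0.131) SoxB1 (-0.79) and Nodal, also adjusted over the list alone. Among germline genes (11, adjusted p = 0.483) FoxY was higher, and among Notch genes (10, adjusted p = 0.656) Delta was higher while Adam10 (-1.06) and Numb (-0.51) were lower. Among early micromere genes (10, adjusted p = 0.852) Delta and Blimp1 were higher and SoxB1 lower. In these 3 lists the counts were the same adjusted over the list alone, and camera pointed up while the medians were negative. Stress genes (17, adjusted p = 0.852) had Jun (0.91) and GadD45 (0.71) higher and both Egr and both Hsp40A models lower, with 3 and 4 adjusted over the list alone, and camera pointed up while median and mean were negative. No cell cycle gene of 32 passed in edgeR, over all genes or adjusted over the list alone (4 had an unadjusted p under 0.05; list adjusted p = 0.656).

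Whether markers share cells was asked with odds ratios within libraries for 15 pairs, in strata of depth. No pair passed the exact sign-flip permutation test with adjustment (lowest adjusted p = 0.0781). The 5 to 7 libraries allow no exact p below 0.0625 to 0.0156, but not every pair reached its limit. Alx1 with scl, over 6 libraries, had an exact sign-flip p of 0.0625 where 0.0313 was possible. For alx1 with gatac the mean log2 odds ratio was 4.29, above 0 in 5 of 5 libraries, with msp130 3.87 (5 of 5), with scl 2.79 (5 of 6), with delta 2.72, with ets1 2.58 and with gcm 2.14 (6 of 6 each). For alx1 with the endodermal endo16 it was 1.67 and with foxa 1.30 (5 of 6 each). It was -0.28 with pks1 (1 of 6 above 0), and -0.082 without 6 hpf, -0.677 without 10 hpf, -0.134 without 14 hpf and -0.160 without 16 hpf. It was -0.95 with the aboral tbx2/3 (0 of 6 above 0) and -1.05 with nodal (1 of 6), and without depth strata -0.53 and -0.72 (2 of 6 each). For gcm it was 3.45 with gatac (5 of 5), 1.78 with foxa (6 of 6) and 1.11 with pks1 (3 of 6; 0.72 without 18 hpf), and for foxa with endo16 1.96 (7 of 7).

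Cells with at least 2 alx1 UMIs, different cells in each library, were profiled from 10 to 18 hpf (22, 12, 76, 381 and 139 cells, median 2673, 5592.5, 7318, 4193 and 4332 UMIs). A UMI of foxa was seen in 45.5, 100, 94.7, 67.7 and 51.8% of them, or 9.52, 83.3, 73.7, 38.7 and 27.3% after thinning to 1000 UMIs. A UMI of gatac was seen in 18.2, 66.7, 78.9, 70.1 and 59.0%, or 9.52, 16.7, 48.7, 50.1 and 38.8% after thinning. The endodermal gene endo16 was seen in 4.55, 91.7, 96.1, 95.5 and 93.5%, and scl in 50, 50, 73.7, 83.5 and 73.4%. The product msp130 was seen in 59.1, 8.33, 14.5, 64.3 and 78.4%, or 47.6, 0, 7.89, 54.6 and 70.5% after thinning. The pigment gene pks1 was seen in 4.55, 0, 0, 0.525 and 1.44%. In aboral ectoderm-like cells from 12 hpf (median 3679, 3905, 2266.5 and 2453 UMIs) the shares were 25.2, 29.9, 37.97 and 32.6% for foxa, 7.99, 11.6, 46.1 and 22.3% for endo16, 0.639, 0.830, 1.54 and 0.966% for gatac, 1.28, 5.60, 10.5 and 6.04% for scl, 0.319, 0.207, 2.13 and 0.845% for msp130 and 0.319, 0.207, 0.355 and 0.604% for pks1. For pks1 the intervals in cells with alx1 (0.0636–1.88% at 16 hpf and 0.175–5.10% at 18 hpf) overlap those of the background (0.131–0.772% and 0.196–1.40%), so a difference was not detectable at this depth. The aboral ectoderm-like class was made mostly of other clusters at 12 and 14 hpf than later. At 10 hpf the 22 cells with at least 2 alx1 UMIs joined 13 skeletogenic-like and 7 endoderm-like cells. Of the 7, 1 held msp130 and 6 foxa, against 12 and 3 of all 14 skeletogenic-like cells.

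**Figure D4:**
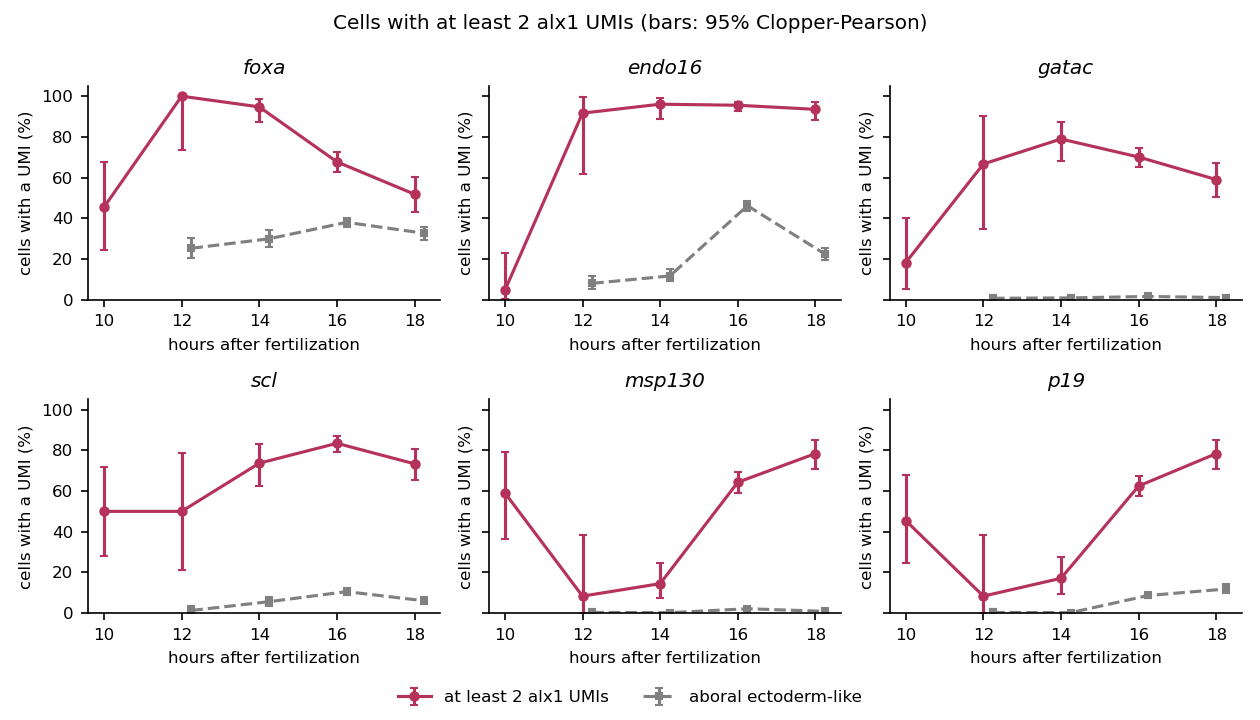
Percent of cells with a UMI of 6 genes against hours after fertilization, in cells with at least 2 alx1 UMIs and in aboral ectoderm-like cells, bars 95% Clopper-Pearson intervals. Among the former foxa was seen in 100% at 12 hpf and 51.8% at 18 hpf, and msp130 in 8.33% and 78.4%.

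Clustering of all cells asked which cell classes the embryos hold, and gave 20 clusters, 14 of them named from markers fixed beforehand. Skeletogenic-like cells made up 0, 0.971, 0.330, 0.647, 3.42 (2.65–4.33), 7.83 (7.24–8.45) and 7.27% (6.44–8.16) of cells from 6 to 18 hpf. The class joins a cluster of 808 cells with 14 of its markers, in which Alx1 stood at 3290 CPM, msp130 at 1516, p19 at 3834 and gatac at 1254, and a cluster of 146 cells, present from 12 hpf, named from Alx1 (2306 CPM), vegfr10 and tbr alone. The smaller cluster held msp130 at 8.62 CPM and p19 at 39.4 CPM, and the blastocoelar genes gatac at 1133 and scl at 3227 CPM, so its name does not rest on products. It made up 0.485, 2.75, 0.818 and 0.666% of cells from 12 to 18 hpf. The cluster of 808 cells also carried 5 blastocoelar markers, gatac, scl, prox1, ese and erg. At 16 hpf 198 cells of the class had no alx1 UMI. Of these 9.60% held msp130, 15.2% p19, 63.6% gatac, 43.4% ese and 84.8% foxa. The name of the class therefore does not mean that each of its cells is skeletogenic. In the class as a whole alx1 was seen in 14 of 14, 3 of 8, 56 of 66, 405 of 603 and 154 of 262 cells from 10 to 18 hpf, and msp130 in 12, 0, 11, 269 and 121 of them. Their share correlated with labelled age by r (0.888, exact permutation p = 0.00754, adjusted p = 0.0377 over 5 classes; 0.844 without the 2 farthest samples) but not by rho (0.857, exact permutation p = 0.0238, adjusted p = 0.119). The call by r ended at resolution 0.5 (adjusted p = 0.0873), at resolution 2 (0.0685), with 1000 variable genes (0.156) and with Scrublet doublets removed (0.236), each an exact permutation, and held with at least 500 genes per cell (0.0377). In those 4 settings the share was 0.207 to 0.570% at 14 hpf, 2.66 to 4.14% at 16 hpf and 2.75 to 4.24% at 18 hpf. Endoderm-like cells made up 0.258, 32.0, 28.3, 18.2, 16.6, 20.7 and 18.6%, oral ectoderm-like cells 0, 17.5, 20.8, 23.1, 21.3, 16.6 and 16.3%, and aboral ectoderm-like cells 0, 20.4, 0, 25.3, 24.97, 21.9 and 23.0%. The aboral shares leave out an unnamed cluster of 817 cells with 5 aboral markers (tbx2/3, hox7, msx, irxa and nk2.2). Its leading genes held 1 marker of another class and no aboral marker. That cluster made up 25.5% of cells at 12 hpf and 24.2% at 14 hpf. Apical and neural-like cells made up 0, 21.4, 24.9, 5.90, 6.01, 8.67 and 7.32%. The endoderm-like, oral ectoderm-like and apical and neural-like classes were made mostly of other clusters at 10 hpf than from 12 hpf on. These shares depended on the clustering too. At resolution 0.5 apical and neural-like cells made up 1.94% at 8 hpf and 0% at 10 hpf, and their r with age was 0.879 (exact permutation adjusted p = 0.0675) against -0.190 (adjusted p = 0.744) at the main settings. With 1000 variable genes aboral ectoderm-like cells made up 0.971% at 8 hpf and 13.3% at 12 hpf, and their r passed (0.949, exact permutation adjusted p = 0.0143) against 0.656 (adjusted p = 0.317) at the main settings. No cluster met the rule for pigment-like, blastocoelar-like, germline-like, ciliary band-like or muscle-like cells at the main settings. With 1000 variable genes, where the skeletogenic-like share at 16 hpf was 2.66%, a blastocoelar-like class held 3.37, 4.67 and 3.30% of cells at 14, 16 and 18 hpf (r with age 0.879, exact permutation adjusted p = 0.0405). At resolution 2 a ciliary band-like class held 3.95 and 7.57% at 16 and 18 hpf (r 0.793, exact permutation adjusted p = 0.0571). Of cells with at least 2 alx1 UMIs, 13 of 22 were skeletogenic-like and 7 endoderm-like at 10 hpf, 3 and 8 of 12 at 12 hpf, and 54 and 19 of 76 at 14 hpf. At 16 and 18 hpf 94.2 and 97.1% were skeletogenic-like.

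Within cells with at least 2 alx1 UMIs at 14, 16 and 18 hpf, those with msp130 were set beside those without (11 and 65, 245 and 136, 109 and 30 cells; median 12693 and 7014, 4269 and 4048, 4323 and 4495.5 UMIs). Foxa was seen in 81.8, 53.9 and 41.3% of those with msp130 and in 96.9, 92.6 and 90.0% of those without. Gatac was seen in 90.9, 62.0 and 49.5% and in 76.9, 84.6 and 93.3%.

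**Figure D5:**
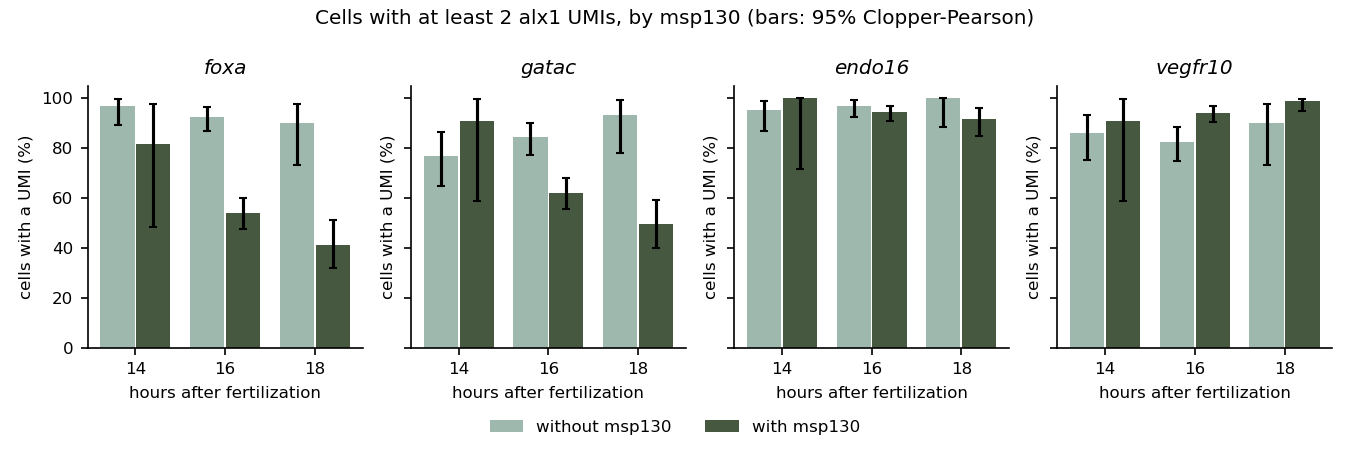
Percent of cells with a UMI of foxa, gatac, endo16 and vegfr10 at 14, 16 and 18 hours after fertilization among cells with at least 2 alx1 UMIs, with and without msp130, bars with 95% Clopper-Pearson intervals. At 18 hpf foxa was in 41.3% of cells with msp130 and 90.0% of those without.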

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

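The tests of how the alx1 difference changes with age, of the order of the libraries, of alx1 with gatac and of the skeletogenic-like cells at 10 hpf were chosen after the results were seen, as were the counts over other orders and splits.

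The difference between cells with and without alx1 changed with age, by a test of the interaction with labelled hours (edgeR, n = 6 libraries, 4 residual degrees of freedom). The make-up of cells with alx1 changed as well: 0, 18.9, 16.7, 48.7, 59.1 and 62.9% of them were skeletogenic-like in these libraries. A change within such cells cannot be told apart here from a change in which cells hold alx1. The log2 fold of cells with alx1 over cells without went up with age for 144 genes and down for 51, whichever its sign, and 1919 had an unadjusted p under 0.05. With 1 library left out the counts were 99 and 30 without 6 hpf, 162 and 15 without 10 hpf, 221 and 67 without 12 hpf, 370 and 94 without 14 hpf, 198 and 26 without 16 hpf, and 223 and 25 without 18 hpf. The biomineralization list moved up as a whole (camera adjusted p = 7.80e-12, 8 members up adjusted over the list alone; adjusted p = 0.324 with an estimated correlation), yet 6 of its 28 members passed over all genes and 22 did not, among them Msp130_1, P19 and P16. The 6 were Sm29 by 0.4287 log2 per hour, the carbonic anhydrase Cara7LA by 0.4451, Clect_14 by 0.4043, the collagens Colp3a by 0.224 and Colp4a_2 by 0.267, and Slc4a10 by 0.1456. Of 17 skeletogenic regulators FoxB (0.4657) and Tel (0.1809) passed, also adjusted over the list alone (camera adjusted p = 3.69e-08; adjusted p = 0.276 with an estimated correlation). The fold of the pigment cell regulator Mitf (0.2001) went up too, as did those of the named genes GrprL (0.2745), B4galt6_8 (0.3486) and Ggdef (0.3397). The hedgehog ligand Hh (-0.4271), Dlx (-0.223), Zic_1 (-0.1743) and both Wnt5 models (-0.1705 and -0.1777) went the other way. Over all 6 libraries the fold was above 0 for Hh (1.61) and below 0 for Dlx (-1.37), Zic_1 (-0.99) and Wnt5 (-0.57 and -0.66). With changes of this size the fold may cross 0 between ages, so these values do not show at which ages a difference widened. By camera the ribosomal list also moved up (adjusted p = 9.90e-07), and the veg1 and Wnt (0.00369), ciliary band (0.00516, with a positive mean), apical and neural (0.0106), aboral ectoderm (0.0191) and endoderm (0.0428) lists moved down, none of these 6 with an estimated correlation (adjusted p = 0.516 each). Without 6 hpf the calls ended for skeletogenic regulators (0.242), ciliary band (0.642), apical and neural (0.730) and aboral ectoderm genes (0.930), and for endoderm without 10 hpf (0.126) or 18 hpf (0.123). The apical and neural list pointed up without 6 hpf.

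The library labelled 8 hpf, not used in the alx1 comparison, held 50 alx1 UMIs, above the limit of 3 that a count of 0 allows. All lay in 1 cell of 13757 UMIs that also held msp130, p19, vegfr10 and erg, and no foxa, endo16 or gatac.

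The library labelled 8 hpf was further along than that labelled 10 hpf. A mixture of cells like those of the other libraries is argued against, as 63.8% of its cells (53.3–73.5) had between 30 and 45% of UMIs from rising genes, and the highest share elsewhere was 25.8% (23.2–28.5) at 12 hpf. Its small cell number is argued against too, as 1000 draws of as many cells from 10 hpf reached at most 20.21% against 39.4%. An exchange of the labels stays open, with 82.1% of 1560 genes of at least 20 CPM further along at 8 hpf. So do embryos of different pace or temperature, which were not tested.

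Gatac was found in many cells with alx1 from 12 hpf on. At 10 hpf it was in 5 of 74 of them (6.76%, 2.23–15.1) against 0.336% of other cells (0.184–0.563). Doublets are argued against as the whole cause from 12 hpf on. The lowest lower bound of the gatac share in cells with alx1 was 26.0% there, and the highest upper bound in other cells 5.81%. At 10 hpf the lower bound of 2.23% lay below that 5.81%, though above the upper bound of 0.563% in other cells of the same library. Cells with both genes were deeper than those with alx1 and no gatac at 14, 16 and 18 hpf, but not at 12 hpf. Their medians were 4943, 7401, 4249.5 and 4616.5 UMIs from 12 to 18 hpf, against 5114, 5405, 3043 and 3854. Doublets as a part of the cause are therefore not argued against. Free RNA is argued against by odds ratios within depth strata, of which the lowest was 3.42 log2. Deeper cells are argued against as the whole cause by the same odds ratios, and by shares after thinning to 1000 UMIs. From 12 to 18 hpf gatac was then seen in 16.7, 48.7, 50.1 and 38.8% of cells with at least 2 alx1 UMIs before thinning. In cells without alx1 it was seen in 0.753, 0.948, 2.51 and 2.38%. Between summed counts of thinned cells the log2 fold of gatac was 4.79, but sums are scaled to their totals, so this fold does not test depth. The pattern may be biological, cells with both a skeletogenic and a blastocoelar regulator, a hypothesis found and tested on the same data.

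At 10 hpf 14 cells were skeletogenic-like: 12 held msp130, 11 p19 and 11 vegfr10, and all 14 tbr, erg, ets1 and delta. Carry-over of cells or RNA from 16 or 18 hpf is argued against, because endo16 was in 0 of the 14 cells, with an upper bound of 23.2%, below the lower bounds in skeletogenic-like cells at 16 and 18 hpf. Micromere descendants left after the operation would carry skeletogenic products and little foxa, and the values go that way. Foxa was in 3 of 14 cells (21.4%, 4.66–50.8) against 53.5% of endoderm-like cells at 10 hpf. Converted cells are not excluded by this, and without unoperated embryos no value decides between the 2.

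For the number of genes with a slope, the labelled order gave 2013. Of 100 orders drawn 1 gave as many, the labelled one itself, while the highest other gave 1975 and the median other 0. Exchanging 8 and 10 hpf, an order not among those drawn, gave more (1698 up and 1945 down). As only some of the possible orders were drawn, with 1 library per age, these counts do not exclude chance. For cells with alx1 the real split gave 1659, 1 of 32 splits gave as many, the real one itself, and the highest other gave 1092. With so few splits these counts do not exclude chance. Cells with alx1 were also fewer and deeper in each of the 6 libraries, which would set the real split apart as well. With cells matched in UMI count 485 genes were higher and 861 lower.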

How the results depend on the processing

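The alternatives with 8 and 10 hpf left out or exchanged, with 14, 16 and 18 hpf alone, with top doublet scores removed and without the deepest barcode were tests chosen after the results were seen; the cause was not tested where a result changed.

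For genes with a slope in time (1012 up, 1001 down), DESeq2 gave 1818 and 1862, counts thinned to the smallest library 453 and 473, and 8 and 10 hpf exchanged 1698 and 1945. With 1 library left out they ranged from 65 to 1323 and from 12 to 1662. The other alternatives, RLE or upper-quartile factors, limma-voom, other filters, log2 hours and doublets removed, stayed within 1.5 times. Lists moving up (5) became 3 without both 8 and 10 hpf and 0 with an estimated correlation, and lists moving down (1) became 0 with an estimated correlation and ranged from 1 to 3 with 1 library left out.

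For cells with alx1 (570 higher, 1089 lower), leaving out the replicate block gave 90 and 3, at least 2 alx1 UMIs 944 and 2068, and 14, 16 and 18 hpf alone 1273 higher genes. With 1 library left out the counts ranged from 246 to 935 and from 599 to 1666. With cells thinned to 1000 UMIs the median log2 fold of all genes was -0.28 instead of -0.07 over 5 libraries, and of the 546 and 848 genes called 285 and 587 were among the 570 and 1089. Lists higher (5) and lower (5) both became 0 with an estimated correlation, and the former ranged from 5 to 8 with 1 library left out.

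The rho of the alx1 share (0.75) was 0.786 with cells thinned to 500 UMIs, past an unadjusted 0.05, and 0.929 with 2000, and ranged from 0.6 to 0.943 with 1 library left out. Markers whose share passed (2) became 4 at 500 UMIs, 7 at 2000, 0 with at least 2 UMIs unthinned, 0 without both 8 and 10 hpf, and 0 to 0 with 1 library left out.

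Clusters (20) became 32 at resolution 2. The r of the skeletogenic-like share (0.888) no longer passed at resolution 0.5 (0.796), at resolution 2 (0.785), with 1000 variable genes (0.729) or with Scrublet doublets removed (0.780). In the same order that share became 0.570, 0.466, 0.207 and 0.469% at 14 hpf, 4.08, 4.14, 2.66 and 3.97% at 16 hpf, and 4.24, 4.16, 2.75 and 3.99% at 18 hpf, and with at least 500 genes per cell 5.76% at 16 hpf and 5.09% at 18 hpf.

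None of the results above reversed past the threshold, but some changed direction. The apical and neural list, whose alx1 difference moved down with age, pointed up without 6 hpf (camera adjusted p = 0.730). The r with age of classes whose correlation did not pass changed sign in some settings. For apical and neural-like cells it went from -0.190 to 0.879 at resolution 0.5. For endoderm-like cells it went from 0.157 to -0.199 with at least 500 genes per cell. Of 387 fold changes of named genes under the alternatives 313 stayed past the threshold and 74 did not, of 423 slopes 387 and 36. All 150 mean odds ratios stayed on the same side of 0, though single libraries crossed it: with Scrublet doublets removed 4 of 5 were above 0 for alx1 with msp130 and 6 of 7 for foxa with endo16. Tbr was the least stable name in cells with alx1, its call also ending under 5 alternatives other than a library left out. Fewer slopes passed with counts thinned to the smallest library, where 9375 gene models were tested instead of 18039.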

Other observations

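The profile by msp130 and the deepest barcode were tests chosen after the results were seen, except that the prediction for foxa with msp130 was written before its result.

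Alx1 also appeared outside skeletogenic-like cells. In endoderm-like cells it was seen in 2.25, 4.89, 11.8, 8.29 and 7.90% of cells from 10 to 18 hpf, against 0, 1.45, 2.49 and 1.45% of aboral ectoderm-like cells from 12 hpf. The latter class was made mostly of other clusters at 12 and 14 hpf than at 16 and 18 hpf. The endoderm-like class changed too. It was a cluster of 1230 cells at 10 hpf, mostly a cluster of 914 cells at 12 and 14 hpf, and mostly a cluster of 1901 cells later. In endoderm-like cells without alx1 endo16 was seen in 9.11% at 10 hpf and 94.9% at 12 hpf. So these shares do not follow the same kind of cell over time. The endoderm-like cells held a median of 2237, 4661, 5216, 3133 and 3477 UMIs and the aboral ectoderm-like cells 3679, 3905, 2266.5 and 2453. At least 2 alx1 UMIs were seen in 0.583, 3.56, 5.92, 1.19 and 0.447% of the endoderm-like cells. Small clusters held other fates. A cluster of 139 cells was apical and neural-like by 7 markers, lhx2/9, hbn, rx, ac/sc, soxc, elav and neurogenin, of which neurogenin and elav belong to neural cells. It made up 0.243% of cells at 12 hpf, 0.570% at 14 hpf, 1.12% at 16 hpf and 1.08% at 18 hpf. A cluster of 96 cells stayed unnamed, with the pigment regulator gcm as its only pigment marker and heat shock gene Hsp701D, Nrl and CebpaL among its leading genes.

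In cells with at least 2 alx1 UMIs, those with msp130 held the endodermal gene foxa less often. Foxa was seen in 81.8% of 11 cells with msp130 and 96.9% of 65 without at 14 hpf, in 53.9% of 245 and 92.6% of 136 at 16 hpf, and in 41.3% of 109 and 90.0% of 30 at 18 hpf. Within depth strata the log2 odds ratio was -2.20, -3.44 and -3.76. In aboral ectoderm-like cells foxa was seen in 29.9, 37.97 and 32.6%. A candidate explanation is that foxa is lost as skeletogenic products come on, a hypothesis these foxa values fit. They do not show a loss, because cells with msp130 that never held foxa would give the same contrast. At 10 hpf 12 of 14 skeletogenic-like cells already held msp130, and 3 held foxa. Cells with and without msp130 may also lie in different clusters, which was not tested. At 14 hpf 19 of the 76 cells were endoderm-like and 54 skeletogenic-like, and msp130 was not a naming marker of the skeletogenic-like cluster of 146 cells. Whether other endoderm genes go the same way was not settled. Endo16, near its ceiling, was seen in 100, 94.7 and 91.7% of cells with msp130. Without msp130 it was seen in 95.4, 97.1 and 100% (log2 odds ratio 0.34, -0.89 and -2.31). With 3 libraries an exact sign-flip test cannot pass 0.05. Gatac went the same way at 16 and 18 hpf (-1.74 and -3.87) and the other way at 14 hpf (1.26), and vegfr10 the other way at 16 and 18 hpf (1.93 and 3.21) but not at 14 hpf (-0.85). Following foxa and msp130 in labelled cells over time would test the order.

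The deepest barcode at 18 hpf held 257816 UMIs, and the next 53703. It held 545 alx1, 508 msp130, 2005 p19, 448 endo16, 183 foxa, 87 scl and 16 gatac UMIs.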
